A study of Homo sapiens with 4 samples.

How the data were processed

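Poly(A)-selected RNA of U87 cells, a human glioblastoma line, was sequenced in 4 libraries: 2 from cells given the vehicle DMSO and 2 from cells given 5 µM of the small molecule YZ129 for 24 h, per the labels' protocols. Samples were grouped by their titles. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between the libraries of the authors' fit, which may be technical.

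The deposited data were 1 table of the authors' own comparison, with no values per library. The submitters' processing notes name TopHat2 2.0.12, Cufflinks 2.2.1, Cuffdiff and the build hg19, without saying which step each served. The columns, per the file headers, are those of a DESeq2 results table; the version, the read counter and the gene annotation are not given in the sources used here. For each of 19749 gene symbols the authors gave a mean level, which is a normalized signal (read counts divided by library size factors), a log2 fold change with its standard error on the log2 scale, a Wald score, a p-value and an adjusted p-value. On these rows the deposited score equalled the log2 fold change divided by its standard error. The deposited p-value equalled the two-sided normal p of that score. The adjusted p-value equalled a Benjamini-Hochberg adjustment over the 14812 genes that had one. The other 4937 genes (25.0%), all with a mean level of 9.43 or less, had no adjusted p-value and were left out of tests.

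The fold changes had been moderated towards 0 before deposit. Genes with only 2 reads, both in the same library of the comparison, had a median change per library of at most 0.55 in size, where an unmoderated ratio has no limit. Folds printed here therefore understate the change of genes with few reads. The median standard error was 0.16 for the 7377 tested genes with a mean level of at least 1000, and 0.45 for the 3086 below 100.

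The lowest mean levels were sums of whole numbers of reads, each read worth a fixed step per library, and these steps were read off the deposited signal. There were 8 of them, and with a tolerance of 1e-07 they gave the mean level of 1372 of 1372 genes with 2 to 5 reads. The authors' mean level was thus taken over 8 libraries, 4 more than the samples described here, and whether these also entered the estimate of the spread is not given in the sources used here. In simulated data with 8 libraries all 8 steps were recovered, and random values met a sum of steps in 0.055% of draws. The size factors of the libraries on the higher side of the comparison came out as 1.01 and 1.17, and those on the lower side as 0.929 and 1.16. Total read counts per library were not analysed here, so no depth in reads, interval on counts or limit for a count of 0 can be given.

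The table does not say which group was the numerator, and the name of the comparison puts DMSO first, which under the usual naming would mean DMSO over YZ129, against the reading used here. A positive deposited log2 fold change was read as higher with YZ129. This reading rests on the cytosolic heat shock list, because the series title places the compound in the HSP90 pathway and loss of HSP90 function is known to release HSF1: 11 called members of that list were positive and 0 were negative. The list was fixed before the data were examined, but its use to read the direction was not. Not every member speaks for this reading: 18 of 29 did not pass, HSP90AA1 and HSP90AB1 stayed close to 0, and PTGES3 was negative. Adjusted over that list alone, 13 were positive and 1 was negative. Under the opposite reading every direction given here turns around and counts and shares of rises and falls trade places, while totals, sizes and p-values stay as they are. The direction of the heat shock list is therefore not a finding.

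The authors' adjusted p under 0.05 was taken as the call, as fixed for a table of this kind at the same point; no test of single genes could be made anew without values per library. Also fixed at that point were 31 gene lists, the list tests, the alternatives and the rule for named genes. For each list with at least 5 tested members, the median log2 fold change was compared with 10000 random lists of the same size from the same deciles of mean level (permutation test, two-sided; the smallest p it can give is 0.0002). A Fisher's exact test (two-sided) compared the share of called genes in the list with that of all other tested genes. Both were adjusted by Benjamini-Hochberg over 30 lists. Genes are not replicates and lists of co-regulated genes vary more than random ones, so these p-values describe the libraries at hand. Among 200 simulated lists of 25 genes for this comparison, drawn over 14812 genes, the permutation test called 5.5% with no shift and 100% with a shift of 0.3, and Fisher's test called 0%, 2% and 95.5% at shifts of 0, 0.3 and 0.6. These rates count unadjusted p under 0.05. The simulated genes varied independently, and outside the list only a small trend with level was put in. Fewer random lists were drawn per simulated test than for the real lists. With so little change outside the list, Fisher's 0% at no shift says little about the real data. Rates for real lists of co-regulated genes may be worse.

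The named genes are the 10 largest rises and 10 largest falls among called genes with a mean level of at least 100, the 3 members of each list with the smallest adjusted p, and all measured members of the heat shock list and of the calcineurin and NFAT list. The mean over the libraries of the fit stood in for the level of the higher group, which the table does not hold. Some genes that the rule selects are not reported here. Genes outside that rule are marked as chosen after their values were seen. Of the symbols, 18969 were found in the RefSeq gene table of GRCh38.p14, which was used for names and transcript classes only; transcript length and GC content came from GENCODE 29 and covered 96.1% of tested genes. No coordinates are printed, because that reference is not the build the submitters named. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.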

Results

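U87 cells were treated with YZ129, which the series title connects with inhibition of the HSP90, calcineurin and NFAT pathway, or with DMSO, and their poly(A) RNA was sequenced (n = 2 libraries per group). HSP90 is a chaperone that keeps client proteins folded; calcineurin is the calcium-dependent phosphatase that lets NFAT transcription factors enter the nucleus. The single comparison asked which transcripts differed after 24 h at 5 µM. All values per gene are the authors' moderated log2 fold changes ± SE, read as YZ129 over DMSO. How many libraries stand behind each SE is not given in the sources used here, since the authors' mean level covers 8. The table does not state that direction, the name of the comparison points the other way, and the heat shock list was used to read it. Under the opposite reading each "rose" becomes "fell" and counts of rises and falls trade places.

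Hypoxia-response genes, glycolytic genes, DNA replication genes and tubulins fell with YZ129, and canonical histone genes rose. Of 14812 tested genes, 1908 (12.9%) passed an adjusted p of 0.05 in the authors' table, whose columns are those of a DESeq2 result; 776 rose and 1132 fell. Among genes that changed by at least 1 on the log2 scale the split was the other way, with 239 higher and 174 lower. The median of all tested genes was -0.05, and it moved with the level: -0.11 for genes with a mean level of at least 1000 and 0.24 for those under 100.

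**Figure D1:**
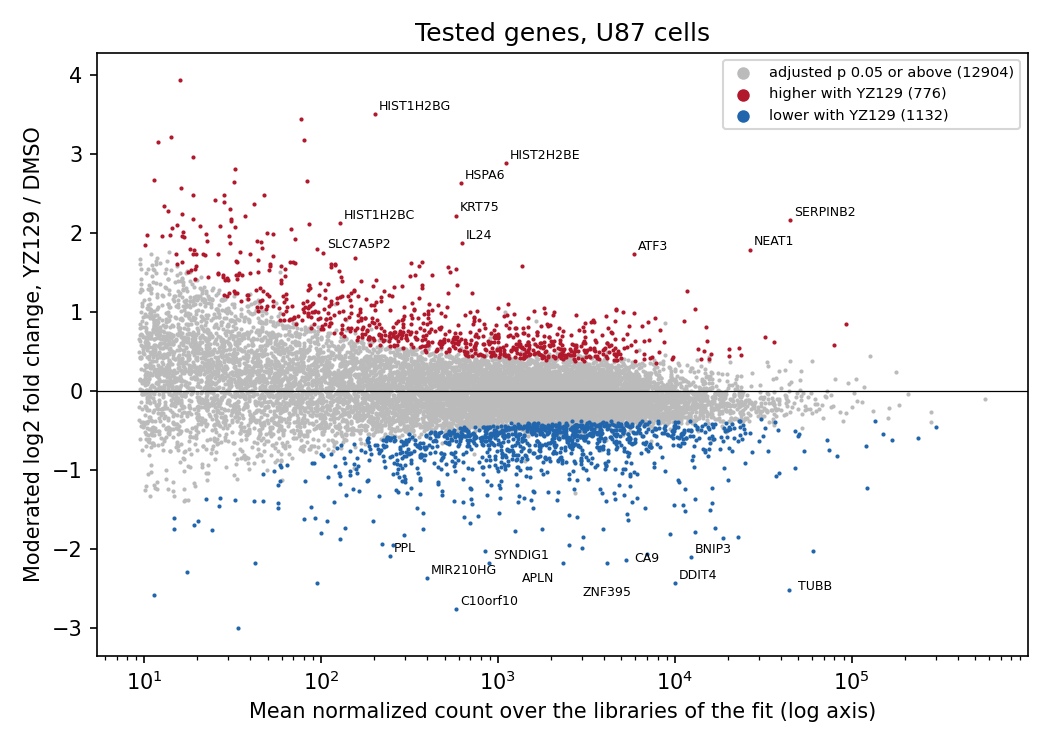
Moderated log2 fold change (read as YZ129 over DMSO) of the 14812 tested genes against their mean normalized count over the libraries of the authors' fit (log axis), 1 point per gene. Red points are the 776 genes that rose, blue points the 1132 that fell, grey points the rest, and the labels mark the 10 largest rises and falls among called genes with a mean level of at least 100.

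The 10 largest rises included 3 H2B histone genes, HSPA6 and ATF3. In the authors' deposited table HIST1H2BG rose 11.4-fold (3.51 ± 0.24) and HIST2H2BE 7.40-fold (2.89 ± 0.16), followed by HSPA6, the strictly inducible HSP70, at 6.22-fold (2.64 ± 0.23). The authors' deposited table then lists the keratin KRT75 (2.22 ± 0.18), the protease inhibitor SERPINB2 (2.17 ± 0.14), HIST1H2BC (2.13 ± 0.27) and the cytokine IL24 (1.87 ± 0.18). Next in the authors' deposited table came the paraspeckle RNA NEAT1 (1.79 ± 0.14), the pseudogene SLC7A5P2 (1.76 ± 0.30) and the stress factor ATF3 (1.74 ± 0.15). SLC7A5P2 and the H2B genes have near-identical copies, so their reads may be shared with those copies. SERPINB2, with a mean level of 44606, and NEAT1, with 26539, were the most abundant of these 10.

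The 10 largest falls included TUBB and the hypoxia-list members CA9 and BNIP3. In the authors' deposited table C10orf10 (now DEPP1) was 6.77-fold lower (-2.76 ± 0.19), the beta-tubulin TUBB 5.74-fold lower (-2.52 ± 0.14) and DDIT4, an mTORC1 inhibitor induced by hypoxia, 5.39-fold lower (-2.43 ± 0.14). The authors' deposited table continues with MIR210HG, the host of the hypoxia-induced miR-210 (-2.37 ± 0.19), SYNDIG1 (-2.18 ± 0.17), ZNF395 (-2.18 ± 0.13) and the peptide hormone APLN (-2.17 ± 0.15). Carbonic anhydrase CA9 (-2.14 ± 0.15), the mitophagy gene BNIP3 (-2.11 ± 0.14) and periplakin PPL (-2.09 ± 0.21) complete the 10 in the authors' deposited table.

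Hypoxia-response genes fell almost as a block. Of 25 tested members 23 fell, 0 rose and 2 did not pass; adjusted over the list alone, 24 fell. The median change was -1.04, below the random lists matched on level (adjusted permutation p = 0.00075, the smallest value reached by any list), and called genes were enriched (odds ratio 78.7, adjusted Fisher's exact p = 1.04e-17). BNIP3, CA9 and the glucose transporter SLC2A1, at 3.50-fold lower (-1.81 ± 0.14), had the smallest adjusted p of the list in the authors' deposited table. The 2 that did not pass, named after their values were seen, were HIF1A itself (-0.14 ± 0.15) and the collagen cross-linker LOX (-0.52 ± 0.20) in the authors' deposited table.

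Glycolytic genes fell with them. Of 21 tested enzymes and transporters 17 fell and 0 rose, or 18 and 0 adjusted over the list alone, with a median of -0.75 (adjusted permutation p = 0.00075). Besides SLC2A1, which is the 1 gene shared with the hypoxia list, the lactate exporter SLC16A3 (-1.48 ± 0.16) and the aldolase ALDOC (-1.48 ± 0.17) had the smallest adjusted p in the authors' deposited table. Components of the PI3K, AKT and mTOR axis showed no such shift: 3 of 28 rose, 5 fell and 20 did not pass, the same counts adjusted over the list alone, and the median of -0.13 lay within the random lists (adjusted permutation p = 0.68; adjusted Fisher's exact p = 0.046, and 0.11 for calls at an adjusted p under 0.01). In the authors' deposited table the receptor PDGFRB (-0.98 ± 0.16) and the translation repressor EIF4EBP1 (-0.85 ± 0.16) fell, and the adaptor IRS2 (1.00 ± 0.17) rose.

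Tubulin transcripts had the lowest median of the 30 lists. Of 12 tested members 10 fell and 0 rose, with the same counts adjusted over the list alone, and the median was -1.79 (adjusted permutation p = 0.00075; odds ratio 34.0). TUBB, TUBA1B (4.07-fold lower, -2.03 ± 0.15) and TUBA4A (4.16-fold lower, -2.06 ± 0.17) had the smallest adjusted p in the authors' deposited table, and TUBB and TUBA1B are among its abundant transcripts, with mean levels of 44495 and 60514. The 2 members that did not pass, named after their values were seen, encode no tubulin: the folding cofactor TBCA (adjusted p = 0.998) and TTC5 (adjusted p = 0.983) in the authors' deposited table.

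DNA replication genes fell, and mitotic genes did so only in part. Of 30 replication and G1/S genes 26 fell and 0 rose (28 and 0 adjusted over the list alone), with a median of -0.62 (adjusted permutation p = 0.00075). The helicase subunits MCM6 (-1.08 ± 0.14) and MCM5 (-1.03 ± 0.15) and the licensing factor CDC6 (-0.95 ± 0.14) had the smallest adjusted p in the authors' deposited table. Of 31 mitosis and G2/M genes 8 fell, 0 rose and 23 did not pass, with the same counts adjusted over the list alone, and the median of -0.15 lay within the random lists (adjusted permutation p = 0.68, but 0.011 for the mean of -0.31). TOP2A (-1.42 ± 0.15), CDK1 (-1.39 ± 0.20) and UBE2C (-1.32 ± 0.17) fell in the authors' deposited table. The difference between the lists was not tested.

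Canonical histone genes rose. Of 13 tested members 10 rose and 0 fell; adjusted over the list alone, 10 rose and 1 fell. The median was 1.35 (adjusted permutation p = 0.00075) and the median level was 114. Over all 50 tested histone genes, a set chosen after the results were seen, 17 rose and 2 fell, and the median was lower, at 0.53. HIST2H2BE, HIST1H2BC and HIST1H2BD (3.07-fold, 1.62 ± 0.21) had the smallest adjusted p of the fixed list in the authors' deposited table. Ribosomal protein genes, included as a sign of RNA quality, gave 0 calls among 41 in the authors' table with DESeq2 columns, 0 also adjusted over the list alone and 0 at an unadjusted p of 0.05, and their median of -0.14 lay within the random lists (adjusted permutation p = 0.82; adjusted Fisher's exact p = 0.021 for fewer calls, and 0.12 for calls at an adjusted p under 0.01). Genes of the mitochondrial genome were not analysed here.

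**Figure D2:**
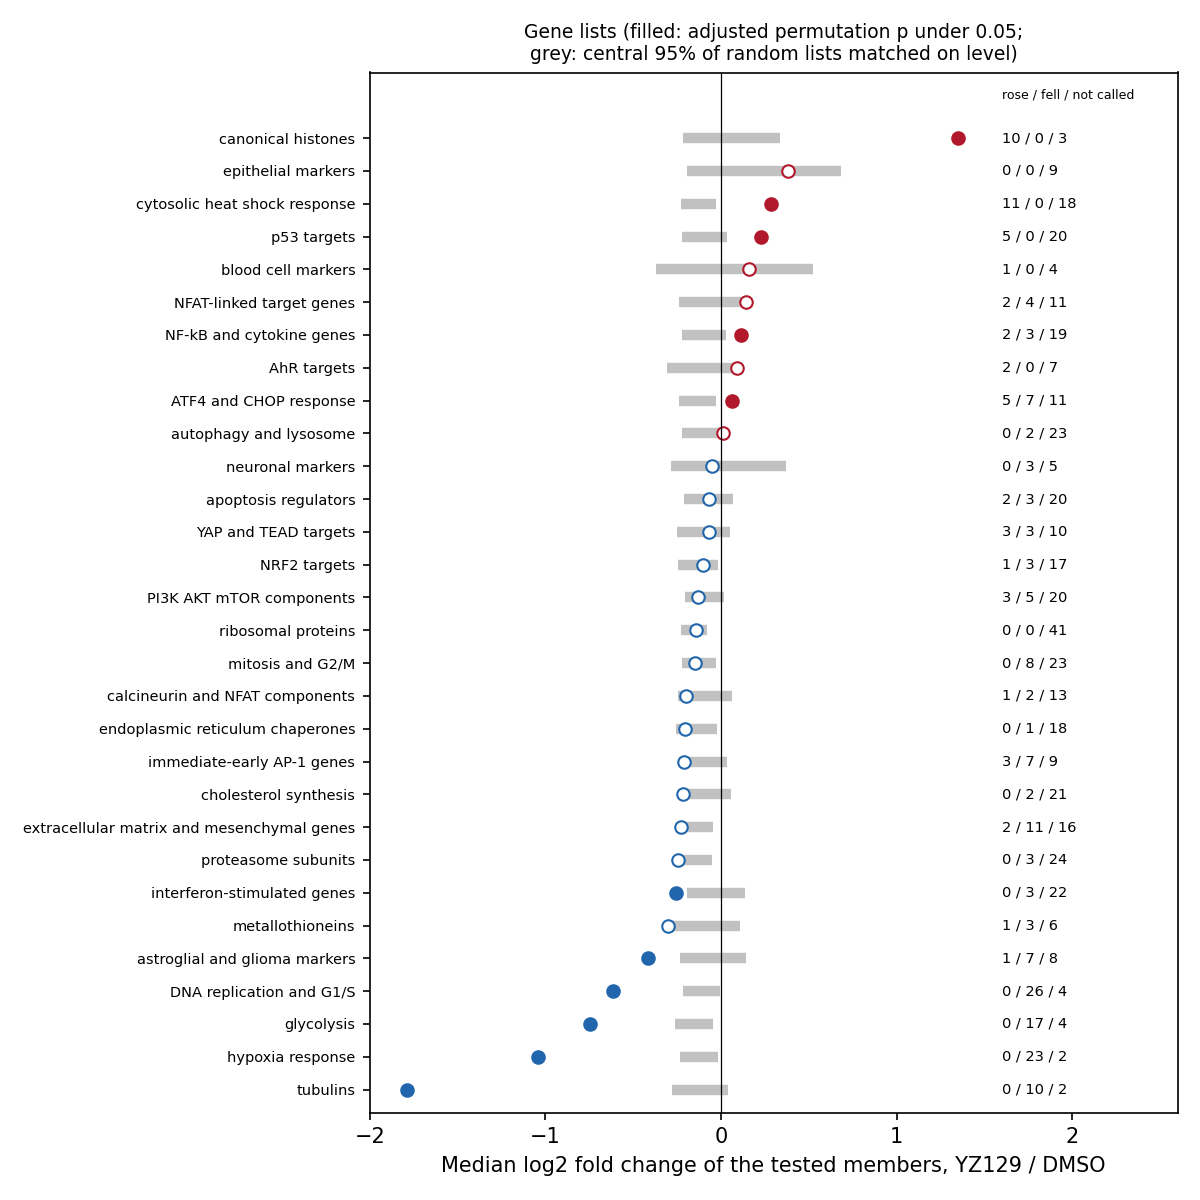
Median log2 fold change (read as YZ129 over DMSO) of the tested members of each of the 30 gene lists with a set test, 1 point per list, with grey bars for the central 95% of random lists matched on level and the numbers of genes that rose, fell or were not called at the right. Filled points passed an adjusted permutation p of 0.05; tubulins lie lowest at -1.79 and canonical histones highest at 1.35.

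The cytosolic heat shock list, used to read the direction of the table, was modest in size. Of 29 tested members 11 rose and 0 fell; adjusted over the list alone, 13 rose and 1 fell. The median was 0.29 (adjusted permutation p = 0.00075). In the authors' deposited table the cochaperone BAG3 (0.99 ± 0.14), CHORDC1 (0.99 ± 0.22), CRYAB (0.91 ± 0.26), HSPH1 (0.88 ± 0.14), DNAJB4 (0.88 ± 0.27) and HSPA1B (0.80 ± 0.15) rose. HSPB8 (0.76 ± 0.15), DNAJA1 (0.63 ± 0.15), HSPA8 (0.58 ± 0.14), DEDD2 (0.53 ± 0.16) and HSPA4L (0.46 ± 0.16) also rose in the authors' deposited table. Both cytosolic HSP90 genes stayed within 1 SE of 0 in the authors' deposited table, HSP90AA1 at -0.04 ± 0.14 and HSP90AB1 at 0.05 ± 0.15. DNAJB1, the main HSP40 partner of inducible HSP70, had 0.39 ± 0.14 and the HSP90 cochaperone PTGES3 -0.47 ± 0.18 in the authors' deposited table, and neither passed. Close to 0 as well were the cochaperones STIP1 (0.04 ± 0.16) and FKBP4 (0.04 ± 0.15) and the factor HSF1 (-0.01 ± 0.16), in the authors' deposited table. HSPA1A, a near-identical copy of HSPA1B with a mean level of only 15.6, had 1.40 ± 0.60 and did not pass in the authors' deposited table; reads may be shared between the copies.

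**Figure D3:**
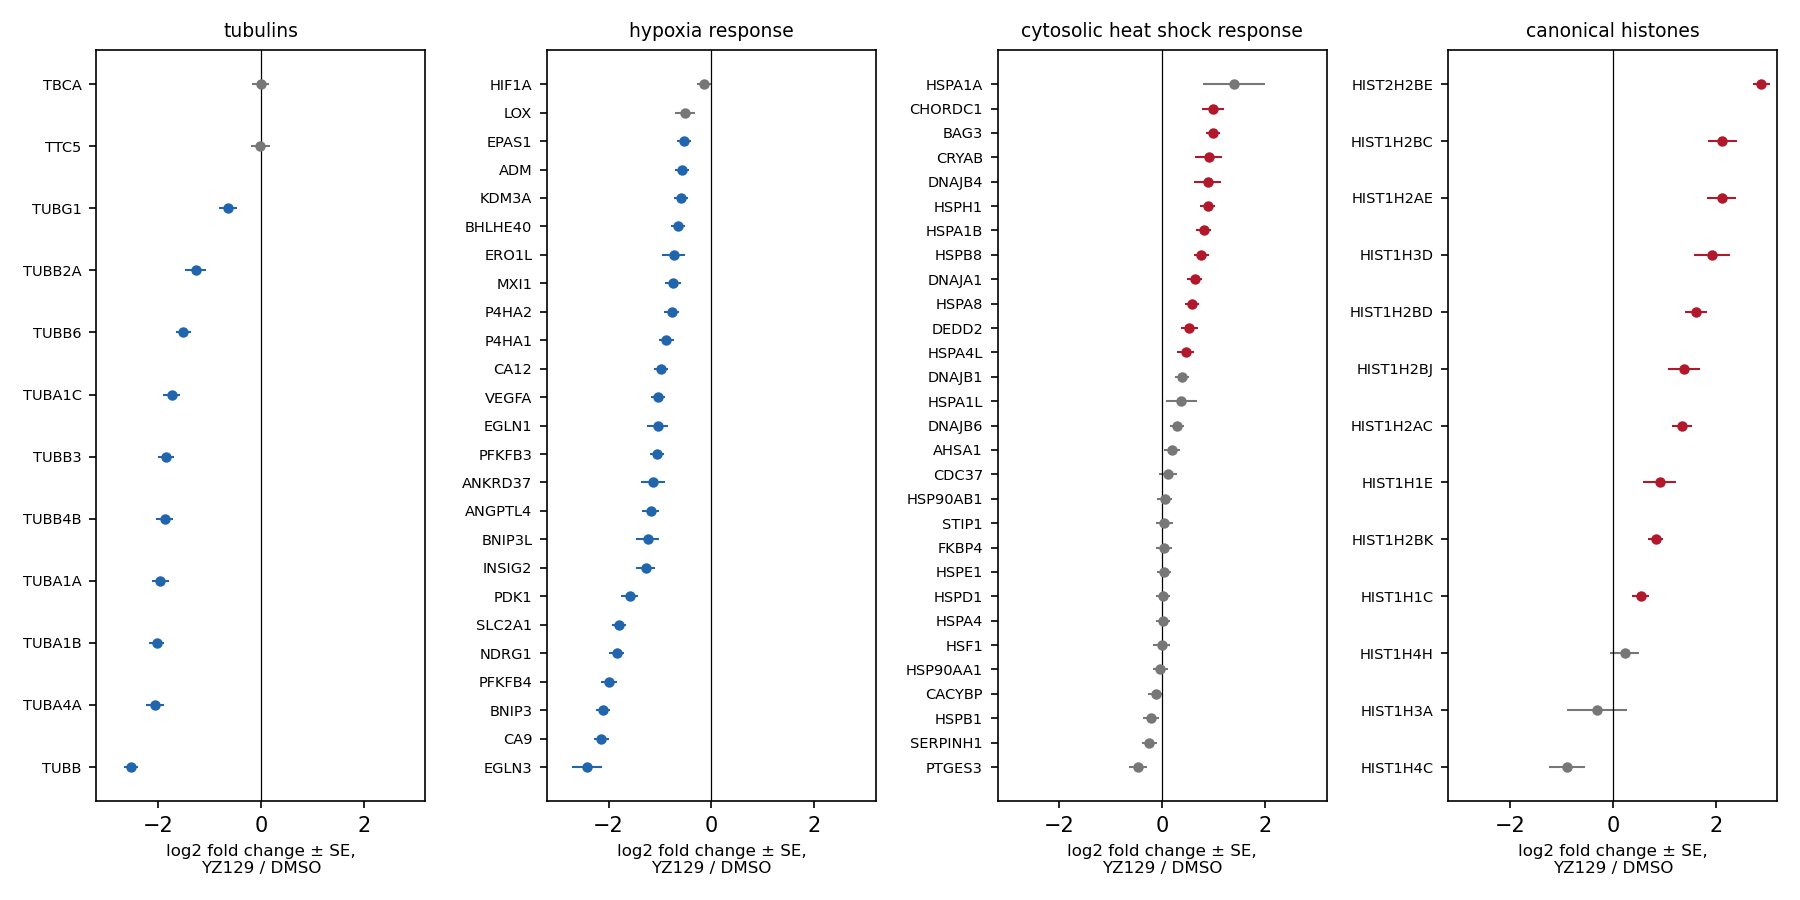
Moderated log2 fold change ± SE (read as YZ129 over DMSO) of each tested member of 4 gene lists, with red for genes that rose, blue for genes that fell and grey for genes that did not pass an adjusted p of 0.05. TUBB lies at -2.52, HIF1A at -0.14 while 23 other members of its list fell, and HSP90AA1 and HSP90AB1 lie within 1 SE of 0.

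Genes of the calcineurin and NFAT machinery itself gave 3 calls. Of 16 tested members 1 rose and 2 fell (2 and 3 adjusted over the list alone), and the median of -0.20 lay within the random lists (adjusted permutation p = 0.26). In the authors' deposited table NFATC2 rose 2.04-fold (1.03 ± 0.18), and the calmodulin gene CALM2 fell (-0.59 ± 0.15). The calcineurin subunits PPP3CA (-0.54 ± 0.23), PPP3CB (-0.23 ± 0.17), PPP3CC (0.14 ± 0.15) and PPP3R1 (-0.28 ± 0.20) did not pass in the authors' deposited table. Nor did NFATC3 (0.13 ± 0.15), NFATC4 (-0.50 ± 0.19), NFAT5 (0.12 ± 0.41) or the calcineurin feedback regulator RCAN1 (0.35 ± 0.14, adjusted p = 0.072) in the authors' deposited table. NFAT-linked target genes went both ways: 2 of 17 rose and 4 fell (7 and 4 adjusted over the list alone), with a median of 0.14 (adjusted permutation p = 0.067; adjusted Fisher's exact p = 0.037). Among members at or above the median level the set test passed (median 0.07, adjusted permutation p = 0.029), and for calls with a log2 change of at least 1 the Fisher call was lost (adjusted Fisher's exact p = 0.20). VEGFA, which the hypoxia list also holds (-1.04 ± 0.13), and EGR2 (-0.82 ± 0.15) fell, while NR4A3 (1.41 ± 0.28) rose in the authors' deposited table.

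ATF4 and CHOP response genes, immediate-early genes and apoptosis regulators held rises and falls alike, while p53 targets that passed all rose. Of 23 ATF4 and CHOP response genes 5 rose and 7 fell (6 and 7 adjusted over the list alone), enriched for calls (odds ratio 7.42, adjusted Fisher's exact p = 3.4e-05). Their median of 0.06 (adjusted permutation p = 0.0013) and mean of -0.09 (adjusted permutation p = 0.65) differ in sign; ATF3 rose and DDIT4 and the lipoprotein receptor VLDLR (-1.24 ± 0.15) fell in the authors' deposited table. Endoplasmic reticulum chaperones, with a median of -0.21 (adjusted permutation p = 0.35), gave 1 fall among 19, PDIA4 (-0.42 ± 0.13 in the authors' deposited table), and the same count adjusted over the list alone. Of 19 immediate-early genes 3 rose and 7 fell (5 and 7 adjusted over the list alone; adjusted Fisher's exact p = 0.0001), with a median of -0.21 (adjusted permutation p = 0.18). EGR1 (-1.35 ± 0.13) and FOS (-1.40 ± 0.18) fell in the authors' deposited table. Among p53 targets 5 of 25 rose and 0 fell, with the same counts adjusted over the list alone and a median of 0.23 (adjusted permutation p = 0.00075), and calls were not enriched (odds ratio 1.69, adjusted Fisher's exact p = 0.49); BTG2 (1.14 ± 0.22), GDF15 (0.62 ± 0.15) and PLK3 (0.50 ± 0.15) had the smallest adjusted p in the authors' deposited table. CDKN1A, the p53-induced cell cycle inhibitor, named after its value was seen, stood at 0.07 ± 0.14 in the authors' deposited table. Of 25 apoptosis regulators 2 rose and 3 fell (3 and 3 adjusted over the list alone), namely BCL2L2 (0.88 ± 0.15) among the former and BID (-0.84 ± 0.14) and DIABLO (-0.54 ± 0.15) among the latter in the authors' deposited table. The median of that list was -0.07 and its mean 0.08, which differ in sign (adjusted permutation p = 0.86).

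Genes on the list of astroglial and glioma markers and matrix genes were mostly lower where they changed. Of 16 astroglial and glioma markers 7 fell and 1 rose (7 and 4 adjusted over the list alone), with a median of -0.42 (adjusted permutation p = 0.00075, but 0.078 for the mean of -0.24). The inhibitors of differentiation ID1 (-1.40 ± 0.14) and ID3 (-1.27 ± 0.15) and the glutamate transporter SLC1A3 (-1.03 ± 0.15) fell in the authors' deposited table. Among the 8 that did not pass there were GFAP (-0.56 ± 0.39), FABP7 (-0.48 ± 0.56) and CHI3L1 (0.15 ± 0.15), named after their values were seen. Of 29 matrix and mesenchymal genes 11 fell and 2 rose (12 and 2 adjusted over the list alone; adjusted Fisher's exact p = 0.0001). Their median of -0.23 did not pass (adjusted permutation p = 0.12), and the enrichment was lost for calls with a log2 change of at least 1 (adjusted Fisher's exact p = 0.45). Collagen COL1A1 (-1.15 ± 0.15), LOXL2 (-1.13 ± 0.14) and TIMP3 (-0.99 ± 0.14) had the smallest adjusted p there in the authors' deposited table. The collagenase MMP1 (0.82 ± 0.14) and the stromelysin MMP3 (0.85 ± 0.15), named after their values were seen, were the 2 that rose in the authors' deposited table. CD44 and VIM are in both of these lists and fell. Of 16 YAP and TEAD targets 3 rose and 3 fell (4 and 3 adjusted over the list alone; adjusted Fisher's exact p = 0.029), and lost that enrichment for calls with a log2 change of at least 1 (adjusted Fisher's exact p = 0.20). Their median was -0.07 (adjusted permutation p = 0.68) and their mean 0.11 (adjusted permutation p = 0.067), which differ in sign, with ANKRD1 10.9-fold higher (3.44 ± 0.36, mean level 77.6) and the coagulation factor F3 lower (-1.52 ± 0.14) in the authors' deposited table.

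Among markers of other cell types, neuronal genes fell in 3 cases and the blood cell marker LCP1 rose. Epithelial markers gave 0 calls among 9 tested in the authors' table with DESeq2 columns and 0 adjusted over the list alone, with 1 at an unadjusted p of 0.05. Blood cell markers gave 1 rise among 5, the actin bundler LCP1 (0.69 ± 0.15 in the authors' deposited table), and the same count adjusted over the list alone. Neuronal markers gave 3 falls among 8, likewise adjusted over the list alone: SNAP25 (-1.43 ± 0.17), ENO2 (-1.12 ± 0.16), which the glycolysis list also holds, and GAP43 (-1.06 ± 0.23) in the authors' deposited table. Against random lists matched on level the epithelial, blood cell and neuronal lists had adjusted permutation p of 0.61, 0.63 and 0.75. Epithelial markers, with a median of 0.38, passed when the lists were not matched (adjusted permutation p = 0.023). Calls among neuronal markers had an odds ratio of 4.06 (adjusted Fisher's exact p = 0.13), and passed at an adjusted p under 0.01 (adjusted Fisher's exact p = 0.038) and with a log2 change of at least 1 (adjusted Fisher's exact p = 0.0065).

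Interferon-stimulated genes and NF-kB genes passed the set test with medians of opposite sign. Calls were enriched in neither list by Fisher's exact test (odds ratios 0.92 and 1.78). Interferon-stimulated genes had 3 falls among 25 and a median of -0.26 (adjusted permutation p = 0.021, but 0.45 for members at or above the median level), with USP18 (-0.68 ± 0.20), OAS3 (-0.57 ± 0.16) and OASL (-0.57 ± 0.17) lower in the authors' deposited table. NF-kB and cytokine genes had 2 rises and 3 falls among 24 and a median of 0.11 (adjusted permutation p = 0.0090, but 0.14 for the mean); TNFAIP3 (0.60 ± 0.14) and IL1A (0.69 ± 0.16) rose and IL6 (-0.53 ± 0.13) fell in the authors' deposited table. Of 9 AhR targets 2 rose, CYP1A1 at 3.23-fold (1.69 ± 0.25) and TIPARP (0.87 ± 0.16) in the authors' deposited table. Among the others, the brain metallothionein MT3 (-2.18 ± 0.43), the proteasome subunit PSMA6 (-0.53 ± 0.15) and the autophagy gene ATG7 (-0.58 ± 0.14) fell in the authors' deposited table. The NRF2 target OSGIN1 (0.67 ± 0.17) rose in the authors' deposited table. Metallothioneins and their regulators gave 1 rise and 3 falls among 10, NRF2 targets 1 and 3 among 21, cholesterol synthesis 0 and 2 among 23, proteasome subunits 0 and 3 among 27, and autophagy and lysosome genes 0 and 2 among 25. The medians of metallothioneins (-0.30, adjusted permutation p = 0.071), AhR targets (0.09, 0.073), NRF2 targets (-0.10, 0.68), cholesterol synthesis (-0.22, 0.090) and proteasome subunits (-0.25, 0.080) did not pass. The means of metallothioneins (-0.42, adjusted permutation p = 0.017) and AhR targets (0.26, adjusted permutation p = 0.0097) did. Nor did autophagy and lysosome genes (adjusted permutation p = 0.071), whose median of 0.012 and mean of -0.038 differ in sign. Adjusted over the list alone, rises and falls were 0 and 3 for interferon-stimulated genes, 4 and 3 for NF-kB and cytokine genes, 2 and 0 for AhR targets and 1 and 3 for metallothioneins. For NRF2 targets they were 3 and 6, for cholesterol synthesis 0 and 1, for proteasome subunits 0 and 3 and for autophagy and lysosome genes 0 and 2.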

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

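The mean level in the authors' deposited table was taken over more libraries than the 4 described here. Reading the value of 1 read in each library off the lowest levels gave 8 libraries, and 4 of them had no weight in the fold change. In 242 of the 1372 genes with 2 to 5 reads, all reads lay in those 4 libraries. How many genes would do so by chance was not worked out. The mean level, which set the matching on level and the level limits above, does cover these libraries. These libraries were not analysed here. No group of 4 or more samples and no second contrast exists in this table, so single libraries that stand apart, or effects that differ between groups, could not be looked for.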

How the results depend on the processing

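The 2 list settings matched on transcript length and on GC content were chosen after seeing the data. The 1908 calls became 1144 (446 higher, 698 lower) at an adjusted p under 0.01 and 413 (239 higher, 174 lower) when a log2 change of at least 1 was also asked for. Benjamini-Hochberg over all 19749 genes gave 1737, and restricting to genes at or above the median mean level gave 1475, of which 458 were higher; fewer genes passed because fewer were tested or more were adjusted for. The share of calls that were higher was 40.7% as reported, 57.9% with the change of at least 1 and 31.1% at or above the median level; under the opposite reading of the direction these are the shares that were lower. Lists past Fisher's test numbered 14, of which ribosomal proteins had fewer calls than other genes, and 9 when a change of at least 1 was asked for. Heat shock genes (1), PI3K components (1), ribosomal proteins (1), NFAT-linked targets (0.20), YAP targets (0.20) and matrix genes (0.45) then lost the Fisher call, and neuronal markers gained one (0.0065). At an adjusted p under 0.01 PI3K components (0.11) and ribosomal proteins (0.12) lost it, and mitosis genes (0.0049), metallothioneins (0.012) and neuronal markers (0.038) gained one. The list of ATF4 and CHOP response genes had a median of 0.06 but a mean of -0.093 (adjusted permutation p = 0.65), and lost its call also without matching on level (0.29); the cause was not tested. With the mean in place of the median the glial markers (0.078) and the NF-kB genes (0.14) lost theirs, the latter also without matching (0.13), while mitosis and G2/M genes (0.011), metallothioneins (0.017) and AhR targets (0.0097) gained one. Without matching on level, matrix genes (0.027), proteasome subunits (0.022) and epithelial markers (0.023) gained one. The interferon-stimulated genes lost theirs among members at or above the median level (0.45), where NFAT-linked targets (0.029) and autophagy genes (0.036) gained one; canonical histones and the epithelial, blood cell and neuronal markers had too few members at that level for a test. Matching on transcript GC changed 0 of the set calls and matching on length added NFAT-linked targets (0.033) and autophagy genes (0.038). Values in parentheses after lists are adjusted p. Recentring on the overall median shifts every gene alike by too little to turn a called gene, so it tests nothing. No paired analysis was possible because the deposited table holds no values per library; for the same reason left-out libraries, other size factors, other count tests and rotation or correlation-adjusted set tests were not run. Depth per library is unknown, and moderation limits what can be said of genes with few reads.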

Other observations

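The tests on histones, on non-coding transcripts, on tubulin isotypes of divergent sequence, on level, length and GC, on cycling cells and on symbol families were chosen after the results had been seen. The sets of actins and of other tubulins were set out before their values were seen, except VIM, TUBG1, TBCA and TTC5. Across 234 families of genes that share a symbol stem and have at least 8 tested members, 14 differed from random lists matched on level. ADAMTS genes, which encode secreted metalloproteases, were higher (5 of 14 rose and 1 fell, median 0.48, adjusted permutation p = 0.0058), with the smallest adjusted p for ADAMTS1 (1.26 ± 0.13) in the authors' deposited table. AKR genes, which encode aldo-keto reductases, were lower (0 of 11 rose and 5 fell, median -0.55, adjusted permutation p = 0.0058), with the smallest adjusted p for AKR7A2 (-0.79 ± 0.15) in the authors' deposited table. Of 420 ZNF genes, mostly zinc finger factors, 36 rose and 9 fell with a median of 0.20 (adjusted permutation p = 0.0058), although ZNF395 was among the 10 largest falls. Among all 14812 tested genes 776 rose and 1132 fell. Of 425 genes with LOC symbols 42 rose and 8 fell (median 0.26, adjusted permutation p = 0.0058), so the shift was not particular to ZNF genes. NBPF genes, a family of near-identical copies, rose in 5 of 8 cases (median 0.64, adjusted permutation p = 0.010).

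The fall of alpha- and beta-tubulin transcripts is a pattern to follow up: 10 of 13 tested isotypes fell, with a median of -1.84. Reads shared between copies are argued against by TUBA4A, TUBB3 and TUBB6, taken as the divergent isotypes, whose median was -1.84. These 3 are among the 13, and the same isotype sets both medians, so the equal values are no independent agreement. Level, length and GC content are argued against by lists matched on them (larger permutation p = 0.00020, the smallest the draws can give). Fewer cycling cells would lower replication and mitosis genes at least as far, but the lowest of 61 such genes was at -1.42 ± 0.15, above the tubulin median (though below TUBB2A at -1.26), and actin and intermediate filament genes had a median of -0.18 (permutation p = 0.0006 against the tubulins). Other tubulins and the tubulin-binding machinery had a median of -0.25 (permutation p = 0.0005), which is what a response specific to alpha- and beta-tubulin mRNAs predicts. Yet 3 of these 20 were lower, the gamma-tubulin TUBG1 among them, so the falls were not confined to alpha- and beta-tubulins. As a hypothesis, the long-known destabilisation of these mRNAs when free tubulin rises may contribute, so a test of YZ129 on microtubules would be informative; under the opposite reading of the direction these mRNAs rose and the mechanism would turn around, and other causes specific to these mRNAs, transcription included, stay open.

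The rise of canonical histone transcripts, 17 of 50 tested genes with 2 falls and a median of 0.53, was also examined. Carry-over of RNA without a poly(A) tail would raise other such transcripts. The 134 small nuclear, nucleolar and similar ones had a median of -0.013, and 0 passed (permutation p = 2e-05 against the histone genes). Their median level was 27.5, near the 35.0 of the 50 histone genes, so moderation towards 0 acted on both. Only 7 of the 134 had a mean level of at least 100, and those had a median of -0.14. Histone genes that rose included some above that level, such as HIST2H2BE (1111) and HIST1H2BG (202) in the authors' deposited table. Moderation may thus have acted less on these. The 73 SNORD genes had a median of -0.061, below random lists matched on level (adjusted permutation p = 0.0058). The 44 SNORA genes had 0.008 (adjusted permutation p = 0.17). The 8 SCARNA genes among them had 0.51, though no member passed (adjusted permutation p = 0.73). Few of the 134 transcripts had a level at which moderation is weak, so their values cannot decide for or against a shared carry-over. Carry-over of histone mRNAs alone stays open too. More cells in S phase would raise replication genes, but that list fell, at -0.62. This argues against more such cells only as far as these mRNA levels track their share, which was not measured. Reads shared between histone copies and a longer, polyadenylated form of these mRNAs were not tested and stay open.

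Long non-coding RNAs and pseudogenes were higher as classes: 95 of 793 rose and 16 fell, with a median of 0.26, against -0.07 for 13387 protein-coding genes. Their low level or length is argued against as the whole cause by protein-coding lists matched on both, which had a median of 0.06 where the 681 with a known length had 0.24 (permutation p = 0.0010, the smallest the draws can give), with 5 bins of level and again with 20, although all tested genes under a mean level of 100 also had a median of 0.24. The 534 whose symbol is unchanged in the reference had a median of 0.25, which argues against unresolved names. Unspliced or nuclear RNA, and reads shared between pseudogenes and their parent genes, may still contribute and were not tested. No biological explanation was tested.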
